A study of Mus musculus with 6 samples.

How the data were processed

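Brain nuclei of wildtype C57BL/6 mice, 6 weeks after sham surgery or 5/6 nephrectomy, were sorted by flow cytometry and captured with the Chromium 3' kit, version 3.1 per the extract protocol, with 10000 nuclei targeted per the labels, on a NextSeq 500. There were 3 sham and 3 nephrectomy libraries. The deposited matrices hold UMI counts per gene and nucleus, 1 matrix per library, as whole numbers. Per the labels, reads were aligned to mm10 with introns included. The Cell Ranger version is 3.0 in the extract protocol, 2.1.1 in the processing notes and 6.0.1 in the matrix headers, and which applies is not known. The extract protocol also names Seurat 4.2.0. No deposited barcode had fewer than 500 UMIs, a limit that the sources do not describe.

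Barcodes numbered 2637, 3102 and 14756 in sham libraries 1 to 3 and 12637, 4424 and 5033 in nephrectomy libraries 1 to 3. Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept (40685 of 42589). Median UMIs per kept nucleus averaged 3499 ± 1760 in sham and 2373 ± 1216 in nephrectomy (mean ± SD of 3 libraries, exact permutation p = 0.4). The difference, -1126, was -424 without nephrectomy 1, -233 without sham 1 and -1992 without sham 3, and -50.7 in named nuclei. Doublets were scored in each library against 2 simulated doublets per nucleus, and the highest-scoring share, 0.8% per 1000 barcodes, was removed after clustering (3513 nuclei), which left 37172. This share grows with the number of barcodes. Called doublets numbered 1742 in sham 3 and 1278 in nephrectomy 1, against 56 to 203 in each of the other libraries. Counts were scaled to 10000 per nucleus and log-transformed. From 2000 variable genes, 30 principal components and 15 nearest neighbours, a shared-neighbour graph was clustered by the Leiden method at resolution 1 without batch correction, which gave 33 clusters.

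A cluster took the class with the highest mean z-score over the first 10 markers of lists fixed beforehand. It was left unnamed where 90% or more of its nuclei came from 1 library, 25% or more were called doublets, its top 10 genes held more markers of another class, fewer than 3 markers were detected in 10% of nuclei, its UMIs were low with no marker of its own among the top genes, or no class scored 0.5. Both percentages were set after the data were seen. With these limits 18 clusters were named, in 11 classes, and 15 were left unnamed. No library was a copy of another.

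UMIs were summed per library and class where a library held at least 20 nuclei, which left 5 libraries for endothelial-like nuclei and 4 for mural-like, fibroblast- or leptomeningeal-like and neuroblast-like or dividing nuclei. In nephrectomy 1, the removal of called doublets had left 26 of 41 endothelial-like and 6 of 20 mural-like nuclei. Summed UMIs ranged from 3646347 to 9000306 per library in excitatory neuron-like nuclei, from 109636 to 685499 in microglia-like nuclei and from 90162 to 502282 in endothelial-like nuclei. Genes were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, filterByExpr), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are nephrectomy over sham, with the standard error, and levels are mean ± SD in CPM (UMIs of a gene scaled to a common library total). Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with camera and an estimated correlation, and with fry. The 4 primary pairs were the interleukin-1 and inflammasome list and the potassium channel and transporter list in microglia-like nuclei, the interleukin-1 receptor and Toll-like receptor list in excitatory neuron-like nuclei, and the blood-brain barrier list in endothelial-like nuclei. Adjustment was over these 4, and over 389 tests for all 34 lists. Shares of nuclei and RNA quality were compared with exact 2-sided permutation tests. Intervals for ratios of pooled counts are exact at 95%, and the floor of a level is 3 counts over the group's total. Gene coordinates came from GENCODE M21 (GRCm38) by Ensembl ID, with 32158 of 32285 found.

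The samples, tests, lists, markers and the other settings to try were fixed before the data were examined, apart from the olfactory bulb genes and the choices said to be later. The genes named in the text are up to 10 per direction and class that passed the test with a mean of at least 20 CPM and no overlap between groups, the 5 genes with the lowest p where fewer than 5 qualified, a fixed set of 64 genes of interest, and up to 4 list members that passed. Some of these genes are not reported here. Any other gene is said to have been named after its values were seen. The other settings were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no filter on low counts, replicate number as a block, a term for the 2 libraries with long barcode lists, the other 4 libraries alone, nuclei with at least 1000 genes, called doublets kept, equal nuclei per library, Leiden resolution 2, other denominators and each library left out. Chosen after the data were seen were clusters rich in doublets included, named nuclei summed alone, named nuclei as the denominator, RNA quality in named nuclei, and the excitatory cluster looked up at resolution 2.

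The gene test was tested on simulated data: negative binomial counts with the means, library sizes and dispersions of each class, 200 changed genes, and 20 random lists of 40 genes of which 1 was raised. Of the 2-fold and 4-fold changes it recovered 50.5% and 94% in excitatory neuron-like, 68% and 97% in inhibitory neuron-like, 59% and 99% in striatal projection neuron-like, 43.3% and 96.9% in astrocyte-like, 35.4% and 100% in oligodendrocyte-like and 40.6% and 99% in oligodendrocyte precursor-like nuclei. It recovered 36.8% and 95.9% in microglia-like, 33% and 91.8% in endothelial-like, 11.1% and 71.7% in mural-like, 13.8% and 75.5% in fibroblast- or leptomeningeal-like, 5.5% and 71.7% in neuroblast-like or dividing nuclei, and 33% and 92% in all nuclei. The changed genes were drawn from genes past the low-count filter, and recovery was counted over those that passed it again. These rates therefore do not cover genes under the filter. False calls numbered 3 to 17 among 82 to 179 calls. The raised list had a camera p of 6.92e-05 or lower in every class, and 0 to 2 of 19 unchanged lists had a p under 0.05. Each simulated gene was drawn independently of the others, so these lists had no correlation between genes. The simulation therefore cannot show whether camera with the preset correlation holds its error rate on real lists. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.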

Results

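Nuclei sorted by flow cytometry from brains of wildtype C57BL/6 mice were profiled by droplet-based 3' RNA sequencing, 6 weeks after sham surgery or after 5/6 nephrectomy, an operation that removes most of the kidney tissue and leads to chronic kidney disease. The series holds 3 sham and 3 nephrectomy libraries, and its design text places the cells in the cortex, though many nuclei had the markers of striatal projection neurons, which lie outside it. The comparison of nephrectomy with sham asks which brain cells change their gene expression in kidney disease, and the series title points to interleukin-1 beta in microglia and to the interleukin-1 receptor in neurons. Total counts were 16018732, 15691316 and 41532967 UMIs in sham libraries 1 to 3 and 33372044, 19831834 and 23152630 in nephrectomy libraries 1 to 3, over 42589 barcodes and 32285 genes. Nothing in the labels states that each library came from a separate animal, so no p-value can be taken to measure the spread between animals. The tests of single genes and of shares measure the spread between these 6 libraries. Camera with a preset correlation compares a list's genes with the other genes. Its p-values rest on the spread between genes taken as nearly independent, and not on the spread between libraries alone.

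Most of the classified nuclei carried neuronal transcripts. Excitatory neuron-like nuclei numbered 7632, striatal projection neuron-like nuclei 4187 and inhibitory neuron-like nuclei 3024. Oligodendrocyte-like nuclei (2642), astrocyte-like nuclei (2065), oligodendrocyte precursor-like nuclei (856) and microglia-like nuclei (858) followed. Endothelial-like (411), mural-like (197), fibroblast- or leptomeningeal-like (206) and neuroblast-like or dividing (357) nuclei made up the rest. The class names rest on marker genes alone, and 22435 of the 37172 nuclei left without called doublets (60.4%) fell in a named class.

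Inhibitory neuron-like nuclei made up 10.9% ± 1.08 of nuclei without called doublets in sham and 6.99% ± 3.26 in nephrectomy (mean ± SD, n = 3 libraries per group, exact permutation p = 0.1, adjusted p = 0.55 over 11 classes). At Leiden resolution 2, where fewer nuclei took the class, the inhibitory shares were 5.36% ± 1.04 and 4.36% ± 2.23 and overlapped between groups (exact permutation p = 0.6). Striatal projection neuron-like nuclei made up 15.7% ± 1.19 and 9.33% ± 4.79 (exact permutation p = 0.1, adjusted p = 0.55). What was dissected from each brain is not known beyond the design text, and differences in dissection were not tested. The value 0.1 is the smallest p that 3 libraries against 3 can give, so no share could pass 0.05. Excitatory neuron-like nuclei stood at 25.8% ± 3.01 and 18.6% ± 10.2 (exact permutation p = 0.3). Of those in sham 3, 37.2% (1251 of 3359) fell at Leiden resolution 2 in a cluster with a median of 1141 UMIs, 82.3% of it from that library, and without them the sham 3 share was 17.7%. Astrocyte-like nuclei stood at 8.05% ± 2.23 and 5.08% ± 3.67 (exact permutation p = 0.4), and microglia-like nuclei at 2.71% ± 1.24 and 1.99% ± 1.11 (exact permutation p = 0.5). In the nephrectomy 1 library, 73.6% of nuclei without called doublets formed a cluster of few UMIs without a class, which lowers all its shares. Counted over named nuclei only, a denominator chosen after the data were seen, the inhibitory share was 13.9% ± 2.07 and 13.4% ± 1.48 (exact permutation p = 0.7), the striatal share 19.9% ± 2.45 and 18.0% ± 3.59 (exact permutation p = 0.6), and the excitatory share turned to 32.8% ± 4.91 and 34.7% ± 7.18 (exact permutation p = 0.9).

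**Figure D1:**
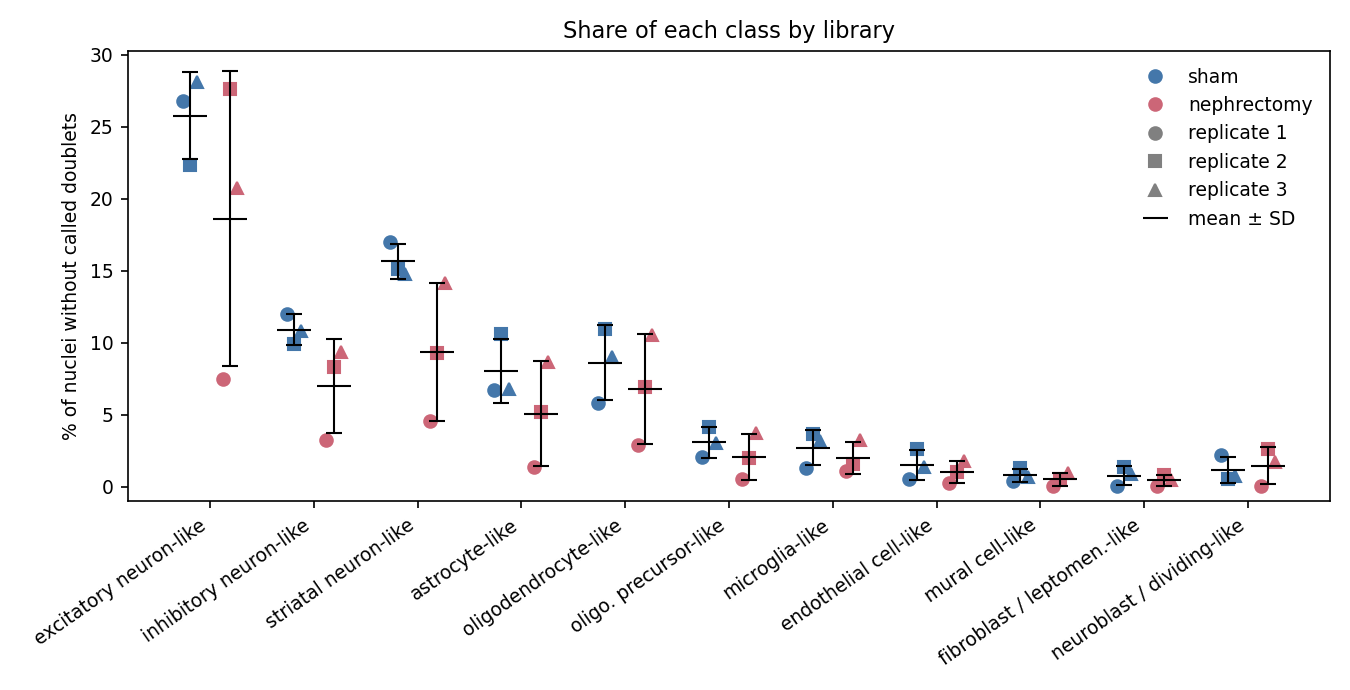
Share of each class among nuclei without called doublets (%, vertical axis) in each of the 6 libraries, with mean and SD per group. All 3 nephrectomy points lie under all 3 sham points for inhibitory and striatal projection neuron-like nuclei, and the nephrectomy 1 library lies lowest in all 11 classes.

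In microglia-like nuclei, the measured genes of the interleukin-1 and inflammasome list were lower after nephrectomy as a group. Of the 19 measured members 13 were lower and 6 higher, with a median log2 fold change of -0.25 (3 libraries per group). Il1b, Il1a, Nlrp3, Casp1 and Casp4 lay under the low-count filter and are not among the 19. Fitted without the filter they stood at 0.02, -0.68, 1.12, -0.73 and -0.02, with standard errors of 0.53 to 1.39. The list fell in a camera test with a preset correlation (adjusted p = 0.00117 over the 4 primary lists). It did not pass with the correlation estimated from the data (p = 0.101 with an estimated correlation). The list's mean log2 level was below every sham library in all 3 nephrectomy libraries. No member passed on its own, with 0 called over all genes tested and 0 called when adjusted over the list alone. Il18, the gene of a second inflammasome-processed cytokine, was at 32.7 ± 11.2 CPM in sham and 13.9 ± 2.30 CPM in nephrectomy (log2 fold change -0.99 ± 0.47 SE, edgeR adjusted p = 0.971), with every nephrectomy library below every sham library. Chance alone separates 3 libraries from 3 in 10% of genes, and the groups were separated in 10.8% of genes in microglia-like nuclei. Pooled over each group, Il18 stood at 28.3 and 14.3 CPM there, against 166 and 181 CPM in astrocyte-like nuclei and 23.9 and 22.3 CPM in all nuclei, so RNA of other cells is not excluded as its source. P2rx7, the ATP-gated channel whose opening triggers the NLRP3 inflammasome, was at 72.5 ± 24.5 and 40.9 ± 14.1 CPM (-0.74 ± 0.34, edgeR adjusted p = 0.971). Aim2, a sensor of cytosolic DNA, stood at -0.89 ± 0.33 and P2rx4 at -0.74 ± 0.27 (both named after their values were seen). Pycard, the inflammasome adaptor, stood at -0.16 ± 0.25, and Casp8 at 0.20 ± 0.37.

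The call on this list ended in 6 alternatives. The adjusted p was 0.203 with an estimated correlation and 0.0981 with fry, which leave the median as it was. In the 4 libraries with short barcode lists it was 0.117 (median -0.19), in nuclei with at least 1000 genes 0.161 (-0.10), with called doublets kept 0.174 (-0.09) and with equal numbers of nuclei per library 0.824, where the median was 0.01 while camera's direction stayed lower. Without the filter on low counts the median was -0.42 and the call held. It also held at Leiden resolution 2 (adjusted p = 0.0229, median -0.26), where only 22 to 152 nuclei per library took the class and clusters with microglial markers stayed unnamed, with 27.2% and 51% called doublets. The adjusted p ranged from 7.49e-05 to 0.824 over all alternatives. In the same nuclei the respiratory chain list had a median of 0.50, the ribosomal protein list 0.30 and the mitochondrially encoded RNA list -0.27. A list of inhibitory synapse genes, which neurons express, also rose there in camera with the preset correlation. Excitatory neuron markers had a median of 0.06 there, with 16 of 29 higher.

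Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139 on the minus strand of GRCm38, protein coding) was almost absent from the counts. It gave 2 UMIs in 518 sham and 2 UMIs in 340 nephrectomy microglia-like nuclei, at 1.24 ± 1.15 and 1.44 ± 2.50 CPM. Pooled over each group this was 1.62 and 1.68 CPM, under the levels of 2.43 and 2.52 CPM that 3 counts would give, and sham astrocyte-like nuclei held 1.83 CPM (5 UMIs). A difference in Il1b was therefore not detectable at this depth, and intervals and floors of this kind cover counting error only. Il1a gave 17 and 10 UMIs, Casp1 9 and 5, Casp4 8 and 8, and Kcnk13, a potassium channel gene, 12 and 9.

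Nlrp3 (ENSMUSG00000032691, chromosome 11, 59541568 to 59566956), the sensor of the NLRP3 inflammasome, also lay under the low-count filter. It gave 14 UMIs in sham and 30 in nephrectomy microglia-like nuclei, at 10.4 ± 2.33 and 24.3 ± 7.61 CPM, and all 3 nephrectomy libraries were above all 3 sham libraries. The pooled ratio was 2.22, with a 95% exact interval for counting error of 1.14 to 4.54. Fitted without the filter, its log2 fold change was 1.12 ± 0.53 (edgeR adjusted p = 0.823), which did not pass. Nlrp3 gave no more than 1 UMI per group in any other class.

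**Figure D2:**
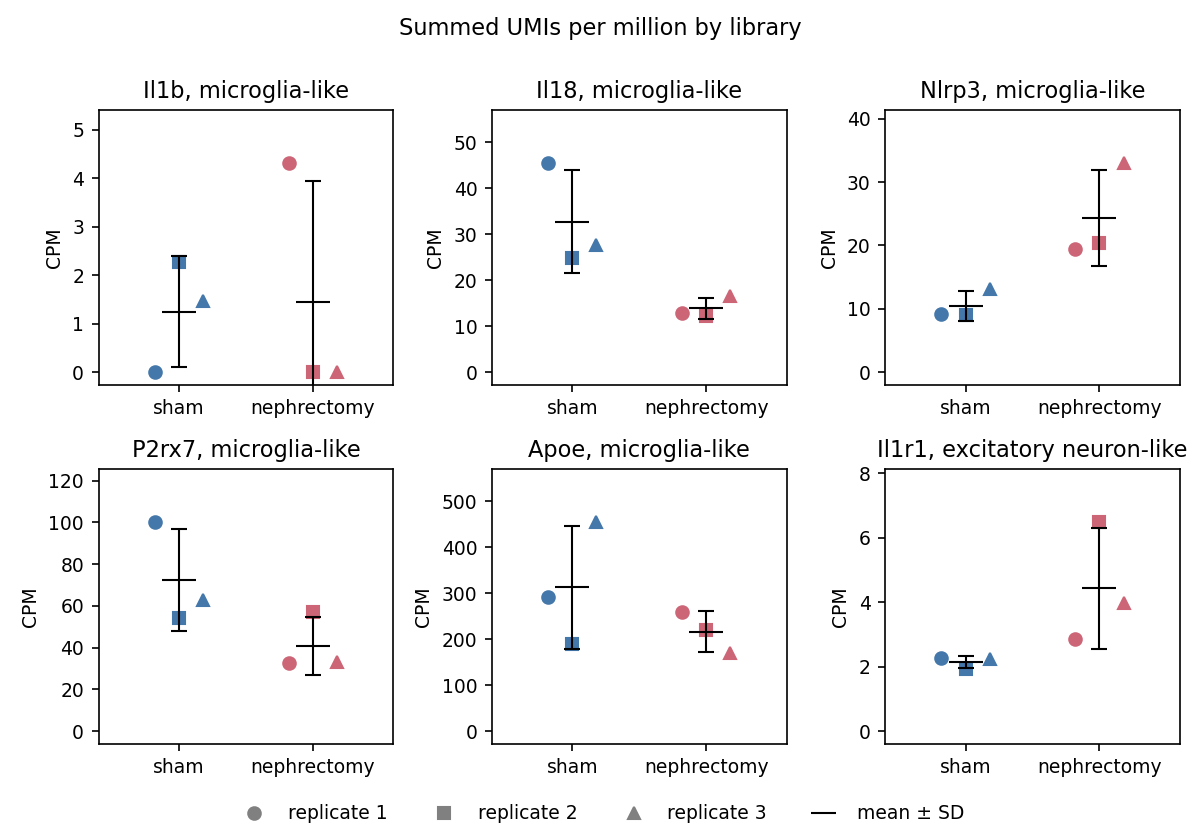
CPM of summed UMIs (vertical axis) of Il1b, Il18, Nlrp3, P2rx7 and Apoe in microglia-like nuclei and of Il1r1 in excitatory neuron-like nuclei, one point per library with mean and SD. Il18 is lower, and Nlrp3 and Il1r1 are higher, in every nephrectomy library than in any sham library, and none of the 6 genes passed the adjusted test. Chance alone separates 3 libraries from 3 in 10% of genes.

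Genes that mark resting microglia did not pass the test. P2ry12 stood at -0.13 ± 0.28, Tmem119 at 0.12 ± 0.32 and Csf1r, the receptor for the growth factor microglia depend on, at -0.01 ± 0.19, while Cx3cr1 stood at -0.41 ± 0.22 (edgeR adjusted p = 0.971). Apoe, which rises in disease-associated microglia, was at 312 ± 134 CPM in sham and 216 ± 45.0 CPM in nephrectomy (-0.57 ± 0.25, edgeR adjusted p = 0.971). Of the homeostatic list 19 of 26 members were lower (median -0.09, camera adjusted p = 0.112 over 389 tests), and the disease-associated list had a median of 0.06. The potassium channel and transporter list, tested because kidney failure disturbs potassium balance, had 31 of 47 members higher (median 0.08, adjusted p = 0.117 over the 4 primary lists, 0 members called over all genes tested and 0 adjusted over the list alone), and did not pass. Among the genes with the lowest p of the 8456 tested were Selenok (1.36 ± 0.33), Ubb (0.87 ± 0.23), Frrs1 (-1.06 ± 0.26) and Abcd4 (-1.56 ± 0.40), and none of these passed the adjusted test in edgeR.

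In excitatory neuron-like nuclei, Il1r1 (ENSMUSG00000026072, chromosome 1, 40225080 to 40317257), the signalling receptor for interleukin-1, was at 2.14 ± 0.19 CPM in sham and 4.43 ± 1.87 CPM in nephrectomy, from 40 and 72 UMIs. All 3 nephrectomy libraries were above all 3 sham libraries (log2 fold change 0.99 ± 0.39 SE), and the test was not passed (edgeR adjusted p = 0.992). Its co-receptor Il1rap stood at -0.12 ± 0.13 and the related Il1rapl1 at -0.25 ± 0.16. In inhibitory neuron-like nuclei Il1r1 lay under the filter with 13 and 15 UMIs, and in endothelial-like nuclei with 12 and 11. The list of interleukin-1 receptor and Toll-like receptor signalling genes had 19 of 28 members lower in excitatory neuron-like nuclei (median -0.11 while the mean was -0.05, camera adjusted p = 0.18 over the 4 primary lists). It did not pass, with 0 members called over all genes tested and 0 adjusted over the list alone. In striatal projection neuron-like nuclei the same list fell (median -0.17, 15 of 23 members lower, camera p = 0.00249), with p = 0.0288 with an estimated correlation, which did not pass over the 389 tests. Whether the 2 neuron classes differ was not tested.

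The glutamate receptor and postsynapse list fell in excitatory neuron-like nuclei (35 of 43 members lower, median -0.12, camera p = 8.74e-05), with p = 0.129 with an estimated correlation. It also fell in striatal projection neuron-like nuclei (33 of 42 lower, median -0.09, camera p = 0.000912), with p = 0.0716 with an estimated correlation. The immediate early genes Fos and Arc stood at 0.43 ± 0.46 and 0.35 ± 0.57, Bdnf at -0.11 ± 0.22 and Camk2a at -0.02 ± 0.12, all within about 1 SE of zero. The interneuron peptides and calcium-binding protein stood at -0.05 ± 0.32 (Sst), 0.27 ± 0.66 (Vip) and 0.35 ± 0.21 (Pvalb). Among the genes with the lowest p in neurons were Tomm5 (0.76 ± 0.17), part of the mitochondrial import pore, and Ntng1 (-0.53 ± 0.12), an axon guidance molecule, in excitatory neuron-like nuclei, and Cycs (0.88 ± 0.19), cytochrome c, and Chd7 (-1.04 ± 0.23) in inhibitory neuron-like nuclei. In striatal projection neuron-like nuclei they included Fth1 (0.67 ± 0.15), the heavy chain of ferritin and Atp5d (0.81 ± 0.19). None of these passed the adjusted test.

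In endothelial-like nuclei, genes of the blood-brain barrier were lower after nephrectomy: 35 of 38 measured members were lower, with a median log2 fold change of -0.43 (2 sham and 3 nephrectomy libraries). The list fell in the camera test with a preset correlation (adjusted p = 2.3e-07 over the 4 primary lists). With the correlation estimated, p = 0.0488 with an estimated correlation, and 0.195 after adjustment. All 3 nephrectomy libraries had a lower mean level of the list than both sham libraries, with a difference of -0.385 ± 0.145. Slc2a1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983), the glucose transporter of the barrier, was at 387 ± 52.0 and 255 ± 41.9 CPM (-0.65 ± 0.25, edgeR adjusted p = 0.993), and turned to 0.24 in nuclei with at least 1000 genes. Cdh5 (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511), the endothelial cadherin of adherens junctions, was at 109 ± 21.4 and 53.9 ± 12.3 CPM (-0.88 ± 0.35, edgeR adjusted p = 0.993). The tight junction genes stood nearer to zero, with Cldn5 at -0.12 ± 0.29 (0.49 in nuclei with at least 1000 genes), Tjp1 at -0.29 ± 0.25 and Ocln at -0.45 ± 0.50, and the efflux pump Abcb1a at -0.28 ± 0.26. No member passed alone, with 0 called over all genes tested and 0 adjusted over the list alone.

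Leaving out the nephrectomy 3 library moved the barrier median to -0.20 (adjusted p = 0.0358), and in nuclei with at least 1000 genes, where 2 libraries per group were left with 20 to 58 nuclei each, it was -0.03 (adjusted p = 0.472), within a range of 1.05e-08 to 0.472 over all alternatives. With called doublets kept the median was -0.20 (adjusted p = 0.00628) and with equal numbers of nuclei per library -0.27 (adjusted p = 0.0285). In the same nuclei, endothelial markers outside the list had a median of -0.33, and Hbb-bs, a haemoglobin gene of red blood cells, stood at -3.21 ± 0.62 (edgeR adjusted p = 0.428).

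In endothelial-like nuclei the interferon response list also fell (11 of 16 members lower, median -0.84, camera p = 1.61e-06), with p = 0.103 with an estimated correlation. The endothelial activation list fell (15 of 20 lower, median -0.38, camera p = 0.000217), with p = 0.0635 with an estimated correlation, and its member Vcam1, an adhesion molecule, stood at 0.10 ± 0.60. Klf4, a transcription factor that keeps endothelium quiescent, was at 216 ± 22.8 and 93.1 ± 32.6 CPM (-1.20 ± 0.29, edgeR adjusted p = 0.993), and Dlc1 and Ushbp1 stood at -1.21 ± 0.30 and -1.31 ± 0.33. In mural-like nuclei (2 libraries per group) the pericyte genes Pdgfrb, Kcnj8 and Abcc9 stood at -0.17 ± 0.33, -0.64 ± 0.40 and -0.44 ± 0.35. The barrier list rose there (21 of 24 members higher, median 0.34, camera p = 0.000646), with p = 0.406 with an estimated correlation. Endothelial markers outside the list were also higher in those mural-like nuclei, with 16 of 17 higher.

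No gene passed the adjusted edgeR test in astrocyte-like nuclei. Simulated 2-fold changes were recovered in 43.3% of cases there, so an absence of change was not shown. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), which rises in reactive astrocytes, was at 36.5 ± 25.7 CPM in sham and 63.5 ± 44.0 CPM in nephrectomy (0.59 ± 0.56, edgeR adjusted p = 0.995), and turned to -0.53 when clusters rich in doublets were included. Aqp4, the water channel of astrocyte endfeet, stood at -0.06 ± 0.23, and the glutamate transporter Slc1a2 at -0.26 ± 0.18. Lcn2 and Serpina3n, markers of reactive astrocytes, lay under the filter, with 1 and 0 UMIs and with 9 and 2 UMIs. The cholesterol synthesis list rose (20 of 23 members higher, median 0.19, camera p = 0.000460), with p = 0.291 with an estimated correlation. Tmem100 (-1.45 ± 0.34) and Uqcrh (1.04 ± 0.27), a subunit of respiratory complex III, were among the genes with the lowest p.

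Myelin genes of oligodendrocyte-like nuclei stood close to zero, with Mbp at 0.00 ± 0.19, Mog at 0.06 ± 0.22 and Mag at -0.15 ± 0.19. Il33, an alarmin that oligodendrocytes express, was at 199 ± 20.7 and 210 ± 41.3 CPM (0.06 ± 0.21). The genes with the lowest p included Tomm6 (1.32 ± 0.30) and Cox8a (0.92 ± 0.24), parts of the mitochondrial import pore and of respiratory complex IV. In oligodendrocyte precursor-like nuclei the precursor markers Pdgfra, Cspg4 and Vcan stood at -0.29 ± 0.22, -0.26 ± 0.20 and -0.45 ± 0.21, and Vcan was lower in every nephrectomy library (edgeR adjusted p = 0.996). Rpl9, a ribosomal protein gene, had the lowest p (1.12 ± 0.28).

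Transcripts of the respiratory chain and of cytoplasmic ribosomes were higher after nephrectomy in all 7 named classes with 3 libraries per group. The classes share the same libraries, so their agreement is not replication. Nuclear genes of the respiratory chain rose with medians of 0.30 to 0.50 log2 units, from excitatory neuron-like (43 of 50 members higher) to oligodendrocyte-like nuclei (48 of 49 higher). Camera gave p between 5.64e-18 and 2.33e-10 per class, and p = 0.123 to p = 0.200 with an estimated correlation, so the calls did not hold there. Ribosomal protein genes rose with medians of 0.29 to 0.48, with 52 of 57 members higher in microglia-like and 56 of 57 in astrocyte-like nuclei (camera p between 1.30e-24 and 7.22e-12, p = 0.0897 to p = 0.18 with an estimated correlation). Without the nephrectomy 1 library the medians were 0.14 to 0.21 for the respiratory chain and 0.17 to 0.36 for ribosomal proteins. The list of 13 mitochondrially encoded genes was lower in excitatory neuron-like (-0.29), inhibitory neuron-like (-0.45), striatal projection neuron-like (-0.43) and microglia-like nuclei (-0.27), and camera gave p = 0.211 to p = 0.413 with an estimated correlation. Over the 7 classes the list's mean change had a median of -0.321, within the median standard error of the classes. The median mitochondrial percentage per nucleus was 0.138 ± 0.0225 in sham and 0.137 ± 0.0458 in nephrectomy (mean ± SD of 3 libraries).

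**Figure D3:**
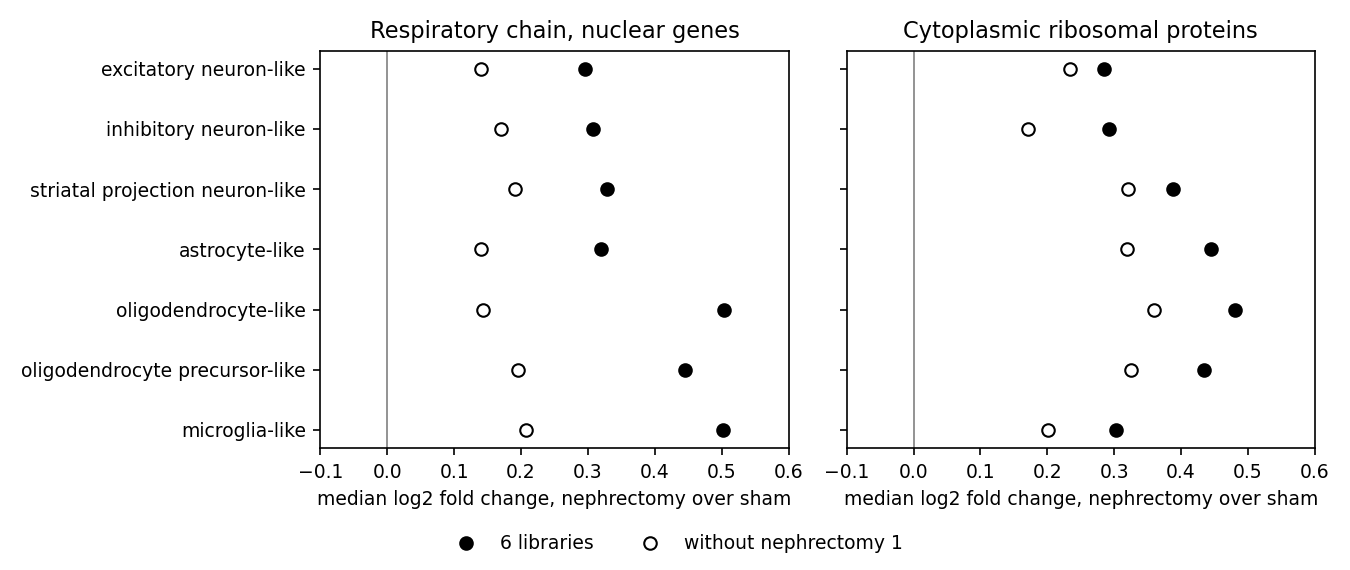
Median log2 fold change, nephrectomy over sham (horizontal axis), of the respiratory chain and ribosomal protein lists in the 7 classes with 3 libraries per group, for 6 libraries (filled) and without the nephrectomy 1 library (open). All medians lie above 0, and those of the respiratory chain fall to between 0.14 and 0.21 without that library.

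Gene by gene, edgeR with its filter on low counts called 0 genes at an adjusted p under 0.05 in each of the 11 classes and in all nuclei together, limma-voom called 0, and DESeq2 called 1 in excitatory neuron-like nuclei (Gh, lower, named after its values were seen) and 1 in microglia-like nuclei. Without that filter edgeR called 21 genes in inhibitory neuron-like, 8 in striatal projection neuron-like and 1 to 11 in 5 other classes, and with the nephrectomy 3 library left out 226 in mural-like nuclei, where 1 nephrectomy library was left. At an unadjusted p under 0.05, edgeR gave 569 of 14630 genes in excitatory neuron-like, 626 of 12776 in inhibitory neuron-like, 528 of 12547 in striatal projection neuron-like and 370 of 9190 in astrocyte-like nuclei. It gave 430 of 8765 in oligodendrocyte-like, 287 of 6845 in oligodendrocyte precursor-like, 415 of 8456 in microglia-like and 324 of 6863 in endothelial-like nuclei. The smallest classes gave 213 of 4557 (mural-like), 336 of 5852 (fibroblast- or leptomeningeal-like) and 113 of 4315 (neuroblast-like or dividing), and all nuclei together 824 of 18160. Chance alone would put a share of about 0.05 of the genes tested under this bound. The counts lay near or below that share throughout, so they are no sign of change. Groups did not overlap in 9.30% to 11% of genes in the 7 classes with 3 libraries per group, where chance gives 10%, and in 19.4% in endothelial-like nuclei, where chance gives 20%. In simulated data of the same depth, 91.8% to 100% of 4-fold changes and 33.0% to 68.0% of 2-fold changes were recovered in the 8 largest classes. These rates hold for genes past the low-count filter only. They do not cover Il1b, Il1a, Nlrp3, Casp1 or Casp4 in microglia-like nuclei.

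Over all 34 lists and 12 groups of nuclei, 57 of 389 tests passed with the preset correlation, 38 higher and 19 lower after nephrectomy. With an estimated correlation 0 passed, and with fry 0 passed. Without the sham 3 library 91 passed, and without the nephrectomy 2 library 87. The balance turned without the sham 2 library, with 24 higher and 32 lower, and was 36 higher and 32 lower without the sham 1 library. In the groups of nuclei with 3 libraries on each side, 40 lists passed with the preset correlation. Other splits of the 6 libraries into 3 against 3 gave 32 to 87. The number of lists that passed is therefore no sign of an effect of nephrectomy.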

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

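Of the tests here, those of neuronal free RNA, of cytoplasm carried over with the nuclei and of a separate cell type were chosen only after the result was seen, and the bound for a separate cell type was changed after its value was known.

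In nephrectomy library 1, 68.0% of barcodes, with called doublets still in, formed 1 cluster without a class, against at most 1.29% in a sham library. The cluster held 8553 barcodes, 97.2% of them from that library, with a median of 906 UMIs against 4616 in its named nuclei. A cell type of its own could not be told apart from other causes, as excitatory neuron markers reached 0.880 of their level in named nuclei and striatal and inhibitory ones 0.630 and 0.591, which neurons of 1 kind may also give, while the 5 other classes reached 0.0230 to 0.136. Droplets with free RNA and no nucleus may explain the cluster, since Malat1, a nuclear RNA, made up 5.88% of its UMIs against 15.5% in named nuclei of the library (ratio 0.379). The cluster was a feature of that library alone, as it held 0.162% and 0.390% of barcodes in nephrectomy 2 and 3 and 1.13%, 0.331% and 1.29% in sham 1 to 3, and an effect of nephrectomy was not tested.

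Respiratory chain and ribosomal protein transcripts were higher after nephrectomy in all 7 classes with 3 libraries per group. Nephrectomy 1 as the whole cause is argued against only weakly. Without it the median over classes of the respiratory chain list was 0.170, against 0.329 with it. The 7 classes share the same libraries, so they do not replicate each other. Whether 0.170 lies beyond the spread between the remaining libraries was not tested. Free RNA of neurons could not be told apart from other causes, as excitatory neuron markers had a median of 0.0712 over the glial classes, while the respiratory chain list made up 1.46% of UMIs in the low-UMI cluster of nephrectomy 1 against 0.434% in that library's named nuclei. More cytoplasm carried over with the nuclei could not be told apart either. The mitochondrially encoded list had a median over classes of -0.321, within the median standard error of the classes, and may follow mitochondria and not cytosol. An effect of nephrectomy stays open.

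Blood-brain barrier genes were lower in endothelial-like nuclei of nephrectomy. Dilution by RNA of other cells may explain this, since endothelial markers outside the list had a median of -0.327. Weight on a single library stays open too, since without nephrectomy 3 the list's median was -0.20 (-0.204) against -0.43 with it. An effect of nephrectomy on the barrier stays open as untested against these.

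Of the 15 clusters without a class, the low-UMI cluster of nephrectomy 1 and those listed here were higher in a nephrectomy library than in any sham library. With 3 libraries per group, chance alone puts the highest library in nephrectomy as often as in sham. The listing is therefore no sign of an effect of nephrectomy. Cluster 9 held 15.6% of barcodes, with called doublets still in, in nephrectomy 2 (highest sham library 13.4%). Cluster 17 held 2.36% in nephrectomy 2 (1.46%), and 30.4% of it were called doublets. Cluster 20 held 2.89% in nephrectomy 1 (0.195%), and 84% of it were called doublets. Cluster 24 held 1.11% in nephrectomy 3 (1.06%). Cluster 28 held 1.62% in nephrectomy 2 (0.624%). Cluster 29 held 1.04% in nephrectomy 2 (0.390%). Cluster 32 held 0.694% in nephrectomy 2 (0.273%). The mean level of the blood-brain barrier list, nephrectomy minus sham, was 0.29 in neuroblast-like or dividing nuclei (4 genes), where both nephrectomy libraries lay above both sham libraries, and -0.38 in endothelial-like nuclei, where all 3 nephrectomy libraries lay below both sham libraries. Not all libraries are in both classes, and the difference was not tested.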

How the results depend on the processing

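Clusters rich in doublets included, named nuclei summed alone, the denominator of named nuclei and RNA quality in named nuclei were the tests chosen only after the result was seen. Of the values under alternatives, 1810 for named genes kept their direction and side of the threshold, 106 turned and 54 passed only under an alternative. For counts of genes called 172 were alike and 32 moved, for primary lists 70 were alike and 9 lost the call, and for shares 119 were alike and 10 turned. The 9 all belong to the interleukin-1 and inflammasome list or the barrier list. The potassium list and the interleukin-1 receptor list had no call to lose, so they count as alike throughout. Clusters rich in doublets included left the values of all 4 primary lists as they were, alike by construction.

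The adjusted p of the interleukin-1 and inflammasome list was 0.203 with an estimated correlation, 0.0981 with fry, 0.117 in the 4 libraries with short barcode lists, 0.161 in nuclei with at least 1000 genes, 0.174 with called doublets kept and 0.824 with equal nuclei per library, in a range from 7.49e-05 to 0.824. That of the barrier list was 0.195, 0.0981 and, in nuclei with at least 1000 genes, 0.472, in a range from 1.05e-08 to 0.472. The number of lists called was 0 with an estimated correlation and 0 with fry, and 47 to 91 with each library left out. The cause was not tested.

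Counts of genes called, 0 with edgeR, became 1 in excitatory neuron-like and 1 in microglia-like nuclei with DESeq2. Without the filter on low counts they became 21 in inhibitory neuron-like, 8 in striatal projection neuron-like, 1 in microglia-like, 4 in endothelial-like, 4 in mural-like, 11 in fibroblast- or leptomeningeal-like and 2 in neuroblast-like or dividing nuclei. With a replicate block they became 1 in mural-like and 10 in fibroblast- or leptomeningeal-like nuclei, and the block could not be fitted in neuroblast-like nuclei. With the term for long barcode lists they became 1 in endothelial-like, 3 in fibroblast- or leptomeningeal-like and 23 in neuroblast-like nuclei. In the 4 libraries with short barcode lists they became 14 in endothelial-like, 1 in mural-like, 8 in fibroblast- or leptomeningeal-like and 27 in neuroblast-like nuclei. Called doublets kept gave 3 in fibroblast- or leptomeningeal-like nuclei and equal nuclei gave 3 in mural-like nuclei. With each library left out they ranged from 0 to 1 in astrocyte-like (highest without nephrectomy 1) and microglia-like (without sham 1), 0 to 5 in endothelial-like (without sham 3), 0 to 226 in mural-like (without nephrectomy 3), 6 to 21 in fibroblast- or leptomeningeal-like (without sham 2 or nephrectomy 2) and 0 to 39 in neuroblast-like nuclei (without sham 1). Where 1 library is then left in a group, it is assumed to vary like the other group. The cause was not tested.

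Differences in shares turned to 1.94 (excitatory), 1.79 (oligodendrocyte) and 0.566 (microglia) with named nuclei as the denominator, and to 1.20 (oligodendrocyte), 0.359 (microglia) and 0.0589 (endothelial) in nuclei with at least 1000 genes. With each library left out they ranged from -3.70 to 0.133 (oligodendrocyte), -0.977 to 0.0722 (endothelial) and -0.276 to 0.979 (neuroblast). Median genes per nucleus differed by 105 in named nuclei, and the mitochondrial percentage by -0.0240 to 0.0218 with each library left out. The cause was not tested.

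With limma-voom and quality weights the sign turned for Homer1 in excitatory neuron-like nuclei (-0.045), Il1rapl1 in inhibitory neuron-like nuclei (0.028), Nfkbia in inhibitory neuron-like nuclei (-0.0059), Sst in inhibitory neuron-like nuclei (0.30), Aqp4 in astrocyte-like nuclei (0.0066), Slc1a3 in astrocyte-like nuclei (0.017), Gja1 in astrocyte-like nuclei (0.10), Kcnk6 in microglia-like nuclei (0.030), P2ry12 in microglia-like nuclei (0.020), Vcam1 in endothelial cell-like nuclei (-0.28) and Acta2 in mural cell-like nuclei (-3.39). With DESeq2 the sign turned for Mbp in oligodendrocyte-like nuclei (-0.0075) and Csf1r in microglia-like nuclei (0.00061). Without the filter on low counts the sign turned for Kcnj10 in astrocyte-like nuclei (-0.018). With replicate number as a block the sign turned for Sst in inhibitory neuron-like nuclei (0.050). With a term for the 2 libraries with long barcode lists the sign turned for Csf1r in microglia-like nuclei (0.011) and Vcam1 in endothelial cell-like nuclei (-0.0016). In the 4 libraries with short barcode lists the sign turned for Nfkbia in excitatory neuron-like nuclei (0.22), Bdnf in excitatory neuron-like nuclei (0.034), Aqp4 in astrocyte-like nuclei (0.055), Csf1r in microglia-like nuclei (0.041), Cldn5 in endothelial cell-like nuclei (0.33) and Ocln in endothelial cell-like nuclei (0.22). Those endothelial cell-like values rest on sham 2 as the only sham library. In nuclei with at least 1000 genes the sign turned for Il33 in oligodendrocyte-like nuclei (-0.16), Pycard in microglia-like nuclei (0.011), Kcnk6 in microglia-like nuclei (0.47), P2ry12 in microglia-like nuclei (0.056), Csf1r in microglia-like nuclei (0.041), Cldn5 in endothelial cell-like nuclei (0.49), Tjp1 in endothelial cell-like nuclei (0.24), Pecam1 in endothelial cell-like nuclei (0.25), Slc2a1 in endothelial cell-like nuclei (0.24), Abcb1a in endothelial cell-like nuclei (0.15) and Vcam1 in endothelial cell-like nuclei (-0.83). With called doublets kept the sign turned for Mbp in oligodendrocyte-like nuclei (-0.049), Il33 in oligodendrocyte-like nuclei (-0.024), Kcnk6 in microglia-like nuclei (0.085), P2ry12 in microglia-like nuclei (0.11), Csf1r in microglia-like nuclei (0.16), Vcam1 in endothelial cell-like nuclei (-0.011) and Pdgfrb in mural cell-like nuclei (0.017). With equal nuclei per library the sign turned for Nfkbia in excitatory neuron-like nuclei (0.092), Camk2a in excitatory neuron-like nuclei (0.0024), C4b in astrocyte-like nuclei (0.15), Il33 in oligodendrocyte-like nuclei (-0.0054), Pycard in microglia-like nuclei (0.53) and Pecam1 in endothelial cell-like nuclei (0.11). At Leiden resolution 2 the sign turned for P2ry12 in microglia-like nuclei (0.12) and Csf1r in microglia-like nuclei (0.29). With clusters rich in doublets included the sign turned for Gfap in astrocyte-like nuclei (-0.53), Kcnj10 in astrocyte-like nuclei (-0.59), Mbp in oligodendrocyte-like nuclei (-0.057), Mog in oligodendrocyte-like nuclei (-0.10) and Il33 in oligodendrocyte-like nuclei (-0.14). The cause was not tested.

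Leaving out each library in turn gave these lowest and highest log2 fold changes. They were found for Nfkbia in excitatory neuron-like nuclei (-0.23 to 0.084), Arc in excitatory neuron-like nuclei (-0.14 to 0.86), Bdnf in excitatory neuron-like nuclei (-0.35 to 0.053), Homer1 in excitatory neuron-like nuclei (-0.17 to 0.26) and Camk2a in excitatory neuron-like nuclei (-0.11 to 0.080). Others were Il1rapl1 in inhibitory neuron-like nuclei (-0.32 to 0.076), Nfkbia in inhibitory neuron-like nuclei (-0.17 to 0.35), Fos in inhibitory neuron-like nuclei (-0.27 to 1.41), Sst in inhibitory neuron-like nuclei (-0.27 to 0.49), Vip in inhibitory neuron-like nuclei (-0.053 to 0.75) and Slc12a5 in inhibitory neuron-like nuclei (-0.013 to 0.15). Others were Gfap in astrocyte-like nuclei (-0.083 to 1.03), Aqp4 in astrocyte-like nuclei (-0.36 to 0.11), Kcnj10 in astrocyte-like nuclei (-0.12 to 0.24), Slc1a3 in astrocyte-like nuclei (-0.23 to 0.044), Gja1 in astrocyte-like nuclei (-0.28 to 0.10) and C4b in astrocyte-like nuclei (-0.49 to 0.30). Others were Mbp in oligodendrocyte-like nuclei (-0.13 to 0.083), Mog in oligodendrocyte-like nuclei (-0.094 to 0.29) and Il33 in oligodendrocyte-like nuclei (-0.14 to 0.18). Others were Pycard in microglia-like nuclei (-0.39 to 0.10), Casp8 in microglia-like nuclei (-0.22 to 0.47), Kcnk6 in microglia-like nuclei (-0.30 to 0.14), Kcnma1 in microglia-like nuclei (-0.035 to 0.22), P2ry12 in microglia-like nuclei (-0.47 to 0.22), Tmem119 in microglia-like nuclei (-0.12 to 0.40) and Csf1r in microglia-like nuclei (-0.18 to 0.078). Others were Cldn5 in endothelial cell-like nuclei (-0.45 to 0.32) and Vcam1 in endothelial cell-like nuclei (-0.64 to 0.68). Others were Acta2 in mural cell-like nuclei (-6.50 to 3.38). The cause was not tested.

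Depth limits Il1b, which lay at or under 3 counts per group in microglia-like nuclei. Il1a, Nlrp3, Casp1, Casp4 and Kcnk13 also lay under the low-count filter there, as did Il1r1 in inhibitory neuron-like and endothelial-like nuclei. Detection of 2-fold changes was limited in large classes too. Among simulated genes past the filter, 68% were recovered in inhibitory neuron-like, 35.4% in oligodendrocyte-like and 33% in endothelial-like nuclei. Recovery was 5.5% to 13.8% in mural-like, fibroblast- or leptomeningeal-like and neuroblast-like or dividing nuclei.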

Other observations

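The test of olfactory bulb genes was chosen only after the result was seen, and its gene list and bounds were written after the values.

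Fibroblast- or leptomeningeal-like nuclei (2 libraries per group) had Ano3 at 1.88 ± 0.36 (edgeR adjusted p = 0.203) and Mgp, a matrix protein gene, at -3.64 ± 0.71. Neuroblast-like or dividing nuclei had Calb2 at 1.94 ± 0.48 and Tubb5 at -1.72 ± 0.49, and neither gene passed the adjusted test in edgeR. Groups did not overlap in 35.4% and 28.3% of genes in these classes and in 34.7% in mural-like nuclei, where chance gives 33.3%.

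In microglia-like nuclei the list of inhibitory synapse genes, which neurons express, rose (18 of 22 members higher, median 0.20, camera p = 0.00129), with p = 0.0814 with an estimated correlation. In their cluster 15.3% of nuclei were called doublets, which were removed. The removal left 377 of 481 nuclei in sham 3 and 122 of 160 in nephrectomy 1. It left 33 of 35 and 108 of 110 in sham 1 and 2. In nephrectomy 2 and 3 it left 67 of 67 and 151 of 160. Excitatory neuron markers had a median of 0.06 in the same nuclei (16 of 29 higher), and whether the UMIs of inhibitory synapse genes came from microglia or from neuronal RNA stays open.

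Clusters 9, 28 and 29, grouped after the data were seen, held 14.6%, 0.170% and 2.85% of nuclei in sham libraries 1 to 3 and 0.183%, 18.5% and 6.45% in nephrectomy libraries 1 to 3. Nuclei of the olfactory bulb are a candidate source of cluster 9. Of 10 olfactory bulb genes, 6 were at least 2 times as high there as in each of 4 named clusters, between the bounds of 8 or more and 2 or fewer, so the test left it open. Cluster 21, which is the whole neuroblast-like or dividing class, reached 5 of the 10 genes, among them Th at 213 CPM. Its top 10 genes held Top2a and Mki67, markers of dividing cells, beside Th, Pax6 and Calb2. Whether that class holds olfactory bulb nuclei stays open too. The olfactory bulb list was run once, set aside after its result was seen and then restored, so it is not an independent test. In cluster 9 Meis2 was at 3482 CPM, Synpr at 212, Sp8 at 59.8 and Th at 27.1, while Pax6 was at 98.4 (238 in cluster 6) and Tbx21 at 0.

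The 6 libraries can be split into 3 against 3 in 10 ways, which is too few for a share under 0.05. In the 8 groups of nuclei that were split, edgeR called 0 genes, so all 10 of 10 splits give as many by construction and these counts decide nothing. The highest count of another split was 2 in inhibitory neuron-like nuclei, 1 in striatal projection neuron-like and microglia-like nuclei and 0 elsewhere. The interleukin-1 and inflammasome list had a p as low in 1 of 10 splits (0.000585, lowest other 0.0153), the potassium list in 1 of 10 (0.0876, lowest other 0.189) and the interleukin-1 receptor list in 3 of 10 (0.18, lowest other 0.0198). At least as many gene lists passed in 9 of 10 splits as in the real one, which is counted among the 9 (40, highest other 87). These counts rest on the preset correlation, and with an estimated correlation 0 lists passed in the real split.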
